A study of Mus musculus with 14 samples.

How the data were processed

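Expression was measured on 14 Agilent mouse arrays (1 colour, design 028005, per the file headers) in 7 groups of 2: D2A1 tumor cells alone, with WT MEFs and with Hsf1 null MEFs, and WT and null MEFs alone and with tumor cells. Per the labels' protocols, the MEFs used with tumor cells that were to be profiled were treated with mitomycin (10 ug/ml, 2 hours), cells were cultured for 72 hours and separated by cell sorting, and 0.5 ug of RNA was labelled per array. Each array held 59305 spots of 55681 probes. All 7 A replicates lay on 1 slide and all 7 B replicates on the other, so replicate letter and slide are the same split.

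The scanner files hold intensity values, which the authors produced with Feature Extraction 10.1.1.1, per the file headers, by subtracting the background and correcting spatial trends, without scaling between arrays. Per the submitters' processing notes the version was 9.1. The authors' value table holds log2 values, deposited as 36553 lines, of which 140 are control spots and 36413 are gene names. How the authors scaled the log2 values between arrays is not stated; array medians lay between 6.33 and 6.40, so the centring used stays unknown, while scale and direction were checked against the scanner values. Against the scanner intensities of genes with several probes, these log2 values correlated best with the mean over all spots of a gene name (r = 0.974, slope 0.945), and less well with the first probe alone (r = 0.923).

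The first design, written before the data were examined, used log2 scanner intensity minus the 75th percentile of each array. The scanner files of 2 arrays, tumor cells with null MEFs A and tumor cells alone A, were faulty: 36.8% and 32.1% of their spots carried outlier flags, against 0.246% to 5.74% on the other 12. Their signals correlated with those of the sound arrays by at most 0.475 and 0.302, where the lowest r among sound arrays was 0.921. Over 117 placements of the grid, shifted by rows and columns, the best r was 0.490 and 0.420, against 0.988 on a sound array. In the authors' value table the lowest r between any 2 arrays was 0.935, so all comparisons used that table. This choice was made from array quality, before any gene was called. The design as first written and the 12 sound scanner arrays were run as alternatives, and their counts stand beside the results. In the first scanner file 55 gene names had been altered by a spreadsheet, so names were taken from the second file.

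Of the gene names, 25827 were tested, those well above background (per the scanner flags) on both arrays of at least 1 group. For the 2 arrays with a faulty scanner file these flags were left out, so the other array of the group decided. On the 14 arrays 38.5% to 63.4% of spots were well above background. A mean of the group values was fitted for each of the 7 groups in 1 model with limma (lmFit and eBayes), giving 7 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. The p-values measure only the spread between these samples. The comparisons were tumor cells with WT MEFs, with null MEFs and between these partners, WT and null MEFs with tumor cells against alone, WT against null MEFs alone and in co-culture, and the difference of the 2 MEF responses. Log2 differences are printed with the SE of the fit. Where a gene was not well above background on either array of a group, the fold is a lower bound. It was taken against the lowest value of any gene well above background on the array, or against the gene's own value where that was higher.

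Before the data were examined, 17 pathway lists and 5 lists of cell type markers were written: cytosolic heat shock, ER stress, TGF-beta response, collagen and matrix, matrix proteases, contractile, inflammatory, interferon-stimulated, hypoxia and glycolysis, DNA replication, mitosis, cholesterol synthesis, p53 target, NRF2 antioxidant, angiogenic, EMT and immediate early genes, and fibroblast, epithelial, macrophage, endothelial, and muscle and neural markers. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 22 lists of a comparison. Also set beforehand were the genes to be named: Hsf1, Tgfb1, Tgfb2, Tgfb3, Cxcl12 and Cxcr4; per comparison the 8 highest and 8 lowest genes that passed with the same sign on both slides and were well above background throughout, and 3 per direction with the highest bound; and up to 4 members per list with the smallest p. Some further list members were named outside this rule, chosen after the results were seen. Results of some genes that the rule or the lists select are not reported here, and counts of named genes or list members include them. Names with a current symbol in the reference table numbered 23707, of which 2907 have another current symbol; names are printed as on the array.

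Carry-over between sorted cell types was gauged by genes at least 32-fold higher in the other cell type grown alone on both slides, and well above background on every array of the higher type (118 genes for tumor arrays, 45 for MEF arrays). The level of the same cell type alone was subtracted on the linear scale from the level in co-culture. The rest was divided by the level in the other type, also less the level alone. That other level came from co-cultured MEFs of the same genotype and replicate letter for tumor arrays and from tumor cells alone for MEF arrays. The MEFs profiled after co-culture had no mitomycin, per the labels, so they came from other cultures than the profiled tumor cells, and mitomycin-treated MEFs were not profiled. The median over the genes was taken as the share. It is an estimate, since such genes could be induced in the cells measured or differ in the source cells. In tumor cells with WT MEFs it runs high where the reference, co-cultured WT MEFs, holds tumor RNA. In 1 alternative this share of the other type's signal in co-culture was subtracted from each co-culture array. The correlation of the tumor-cell responses was compared with 20 simulations of unchanged groups against the same controls.

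The fit was tested on simulated data for tumor cells with WT MEFs against alone (25827 genes): 81 of 100 genes changed 2-fold and 97 of 100 changed 4-fold were recovered, 9 unchanged genes were called, and the shifted list was called with 0 others. Mixed shares of 8%, 20%, 30% and 5% were recovered as 11.3%, 21.2%, 29.6% and 4.9%. Alternatives were quantile scaling, normexp background correction, no filter, a stricter filter, the slide as a block, each cell type fitted alone, a mean of probes, an intensity trend in eBayes, each array left out, and 10 added after the data were seen, 1 of them the design as first written. Software was R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probe positions are on mm9, per the file headers.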

Results

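Gene expression was measured in D2A1 cells, a mouse breast cancer line, and in mouse embryonic fibroblasts (MEFs) that were wild type (WT) or lacked Hsf1, the gene of the heat shock transcription factor. Tumor cells and MEFs were cultured together for 72 hours and then separated by cell sorting, and each cell type was also grown alone. The 14 arrays formed 7 groups of 2, with all A replicates on 1 slide and all B replicates on another. On the 12 arrays with a sound scanner file, 53.1% to 63.4% of 59305 spots lay well above background, and only 2 arrays per group limited the precision of every value. Values below are log2 differences ± SE with n = 2 arrays on each side unless stated otherwise. The SE and p use 1 variance per gene from all 7 groups, so spread outside the comparison counts too. Every gene that passed had the same sign on both slides.

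Hsf1 mRNA was lower in the null MEFs than in WT MEFs, but its probe signal stayed above background. Its mean log2 signal was 11.85 ± 0.22 (SD, n = 2) in WT MEFs alone and 10.02 ± 0.07 in null MEFs alone, a difference of 1.83 ± 0.12 (3.56-fold, adjusted p = 1.11e-06, limma). In co-culture the difference was 1.45 ± 0.12 (2.74-fold, adjusted p = 1.02e-05). Tumor cells alone had 12.83 ± 0.03, and co-culture with null MEFs lowered this by -0.46 ± 0.12 (adjusted p = 0.0231). Co-culture with WT MEFs did not change it (-0.08 ± 0.12, adjusted p = 0.736). Null MEFs rose by 0.58 ± 0.12 in co-culture (adjusted p = 0.0271). The fall of Hsf1 in tumor cells did not pass after the MEF share was subtracted (-0.26, adjusted p = 0.218), without null-partner tumor cells B (-0.39, adjusted p = 0.135) or without tumor cells alone A (adjusted p = 0.0882) or B (adjusted p = 0.0683). Its rise in null MEFs did not pass after subtraction (0.26, adjusted p = 0.756), without null MEFs with tumor cells B (0.50, adjusted p = 0.151) or without null MEFs alone A (adjusted p = 0.0998) or B (adjusted p = 0.22). The Hsf1 probe (A_55_P2035593) lies on chromosome 15 at 76331320 to 76331379 (mm9, per the file headers), and whether this is inside the deleted part was not recorded.

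**Figure D1:**
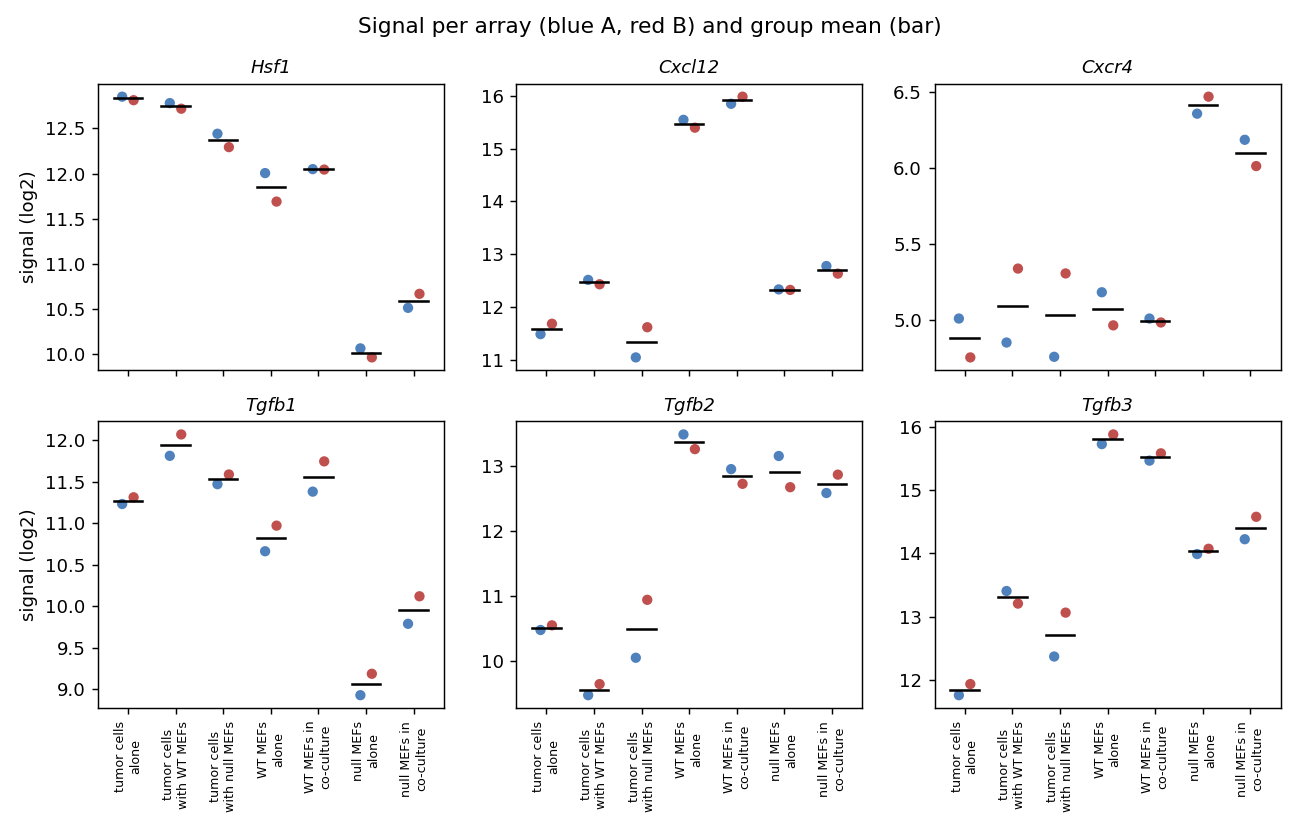
Log2 signal of Hsf1, Cxcl12, Cxcr4, Tgfb1, Tgfb2 and Tgfb3 in the 14 arrays (points; A blue, B red) with the mean of each group (bars). Hsf1 lies at 10.02 in null MEFs alone and 11.85 in WT MEFs alone, and Cxcl12 at 12.33 and 15.47.

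The first comparison asked what WT MEFs changed in the tumor cells. Col3a1 rose by 7.36 ± 0.50 (164-fold, adjusted p = 1.08e-05), and Col1a2 and Col1a1, the chains of type I collagen, by 5.65 ± 0.39 and 5.43 ± 0.35. Among other genes, Rcn3 rose by 6.57 ± 0.26, Fstl1 by 6.45 ± 0.33, Serpinf1 by 5.03 ± 0.38 and Wisp2 by 4.91 ± 0.49. The chemokine Ccl7 rose by 5.23 ± 0.42 (37.4-fold, adjusted p = 3.14e-05), Ccl2 by 4.27 ± 0.41 and Ccl5 by 4.21 ± 0.27. From near background in tumor cells alone, Penk rose at least 677-fold, Bicc1 at least 153-fold and Plxdc2 at least 119-fold. Less the MEF share, Bicc1 (-0.28) and Plxdc2 (-0.33) no longer passed. Klhl30 (-2.42 ± 0.20), Trim54 (-2.38 ± 0.19), Macc1 (-1.97 ± 0.18), Ankrd1 (-1.95 ± 0.11), Tigit (-1.87 ± 0.21), Gsta1 (-1.85 ± 0.21), Fgd3 (-1.83 ± 0.19) and Edn1, the precursor of endothelin 1 (-1.82 ± 0.25), fell the most, with adjusted p from 3.44e-06 for Ankrd1 to 0.000954 for Edn1. Of the genes near background after co-culture, Vmn2r11 fell at least 4.53-fold, Tbxas1 at least 2.92-fold and Olfr1065 at least 2.74-fold. Vmn2r11 did not pass without tumor cells with WT MEFs B (-1.94, adjusted p = 0.0864).

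Of 28 interferon-stimulated genes measured with WT MEFs, 24 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 2.09, among them Ifit1 (3.81 ± 0.14), Usp18 (4.14 ± 0.21) and Mx2 (3.67 ± 0.23). Camera gave adjusted p = 1.55e-36, and adjusted p = 0.0654 with an estimated correlation. Collagen and matrix genes had 16 of 23 higher and 0 lower (18 and 0 over the list alone). The list median was 2.25 (adjusted p = 6.82e-17, 0.0672 with an estimated correlation). Lox rose by 3.94 ± 0.37 and Postn by 4.50 ± 0.82. Fibroblast markers had 15 of 19 higher and 0 lower (16 and 0). Its median was 1.05 (adjusted p = 2.18e-15, 0.0654 with an estimated correlation). In these tumor cells the 118 genes at least 32-fold higher in MEFs lay at a median of 7.64% (A) and 7.43% (B) of their MEF level, less the level in tumor cells alone. The 22 of 23 collagen genes at least 2-fold higher in MEFs lay at 5.98% and 7.89%, and all 28 interferon-stimulated genes at a median of 74.4% and 75.1%.

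Matrix proteases and their inhibitors had 10 of 18 higher and 4 lower (11 and 4 over the list alone) with WT MEFs. Mmp2 rose by 4.33 ± 0.33, Mmp3 by 3.15 ± 0.11 (adjusted p = 5.59e-07) and Mmp9 by 2.65 ± 0.22. The list median was 0.50 (adjusted p = 0.000136, 0.0672 with an estimated correlation). EMT regulators had 7 of 13 higher and 0 lower (7 and 1), with Cdh2 at 3.40 ± 0.28 and Twist2 at 2.93 ± 0.35. The list median was 0.50 (adjusted p = 0.000136, 0.0654 with an estimated correlation). TGF-beta response genes had 8 of 16 higher and 1 lower (10 and 2). Tgfb1i1 rose by 3.91 ± 0.24 and Ctgf by 2.52 ± 0.25, and the median was 0.78 (adjusted p = 1.86e-05, or adjusted p = 0.151 with an estimated correlation). Inflammatory genes had 10 of 19 higher and 2 lower (10 and 2). Its median was 0.55 (adjusted p = 7.65e-05, 0.25 with an estimated correlation).

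Hypoxia and glycolysis genes had 7 of 25 lower and 1 higher with WT MEFs (11 and 1 over the list alone), with a median of -0.32. Hk2 fell by 1.09 ± 0.13 and Ndrg1 by 1.01 ± 0.12, whereas Car9, a carbonic anhydrase, rose by 2.36 ± 0.16. The list had adjusted p = 0.000103 (0.0654 with an estimated correlation). Among 21 cytosolic heat shock genes 3 were lower and 0 higher (6 and 0), namely Cryab (-1.12 ± 0.13, adjusted p = 0.000357), Hspb1 (-0.69 ± 0.18) and Hspd1 (-0.47 ± 0.12). Their median was -0.25 (adjusted p = 0.016, or adjusted p = 0.151 with an estimated correlation), and the call ended without tumor cells with WT MEFs B (adjusted p = 0.0949) or tumor cells alone A (adjusted p = 0.101). DNA replication genes had 3 of 24 lower, such as Ccne1 (-0.49 ± 0.09). The list median was -0.14 (adjusted p = 0.0233, 0.151 with an estimated correlation). ER stress genes had 4 of 16 lower (5 over the list alone), such as Sdf2l1 (-0.77 ± 0.15). Its median was -0.21 (adjusted p = 0.0472, 0.151 with an estimated correlation). DNA replication genes did not pass without tumor cells with WT MEFs A (adjusted p = 0.082) or tumor cells alone A (0.051), nor ER stress genes without tumor cells with WT MEFs B (0.0864) or tumor cells alone A (0.114), nor with the slide as a block (0.0652). Epithelial markers did not pass (0 of 18 higher, 2 lower, adjusted p = 0.118), nor did NRF2 antioxidant genes (3 of 16 higher, 1 lower, adjusted p = 0.986).

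In this comparison 3051 of 25827 tested genes passed (limma, adjusted p under 0.05), 1820 higher (59.7%) and 1231 lower, of which 834 and 139 changed at least 2-fold. With the slide as a block 4163 passed, on the 12 sound scanner arrays 825 (91.9% higher, with a median shift of all genes of 0.107), and on all 14 scanner files as first designed 42. Each cell type fitted alone gave 1274 (74.8% higher), and Tgfb1, Tgfb2, Cxcl12, Vmn2r11 and Olfr1065 did not pass there. Without the genes at least 2-fold higher in MEFs 1472 passed, 551 higher (37.4%) and 921 lower. With the MEF share subtracted, 1310 passed and 16 of 26 named genes kept their call. Rcn3, set to the floor, passed as lower (-1.33). Fstl1 (-1.27), Wisp2 (-1.52), Serpinf1 (2.99), Ankrd1 (-1.89) and Col3a1 (3.69, adjusted p = 0.259) no longer passed. Serpinf1, Ankrd1 and Col3a1 kept their direction, and spread that subtraction adds in any group can end a call. The collagen list (median -0.19, adjusted p = 0.17) and the heat shock (0.0624), DNA replication (0.142) and ER stress (0.0947) lists did not pass. On the 12 scanner arrays the lists of proteases (adjusted p = 0.0992), hypoxia (0.105), DNA replication (0.116) and ER stress (0.116) did not pass.

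**Figure D2:**
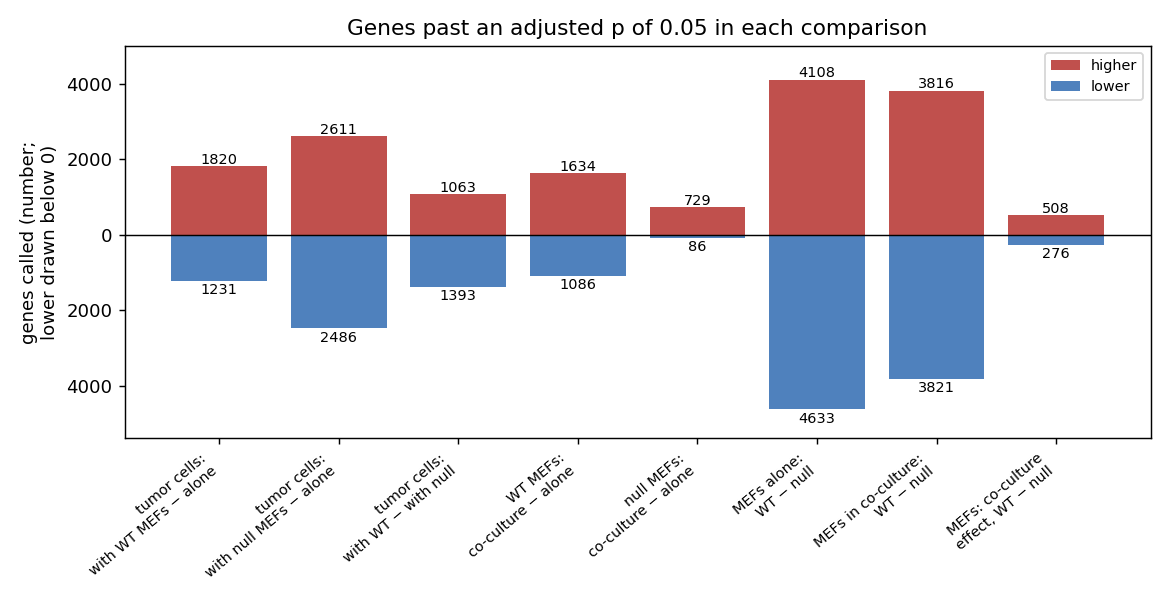
Number of genes past an adjusted p of 0.05 in each of the 8 comparisons, higher above 0 and lower below 0. Co-culture with null MEFs changed 2611 genes upward in tumor cells and co-culture with WT MEFs 1820, while co-culture changed 729 upward in null MEFs.

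The second comparison asked the same of null MEFs. Ccl7 rose by 9.25 ± 0.42 (609-fold, adjusted p = 1.48e-07), Ccl2 by 7.78 ± 0.41 and Ccl5 128-fold (adjusted p = 5.59e-08). Irf7, a transcription factor of the interferon response, rose by 8.52 ± 0.29, Ifit3 by 8.29 ± 0.22, Gbp3 by 7.94 ± 0.16 and the surface protein gene Ly6a by 7.74 ± 0.26. From near background, Ifi44 rose at least 784-fold, Oas2 at least 691-fold and Usp18 at least 487-fold. Col3a1 rose by 7.86 ± 0.50 and Fstl1 by 7.63 ± 0.33. The genes that fell the most were Pcdha9 (-2.37 ± 0.66), H60b (-2.09 ± 0.19), Actg2 (-2.08 ± 0.27), Ctsw (-1.87 ± 0.17), the tight junction gene Cldn3 (-1.86 ± 0.24), Macc1 (-1.75 ± 0.18), Edn1 (-1.72 ± 0.25) and Snora74a (-1.69 ± 0.24). Vmn2r11 fell at least 4.5-fold, Vmn1r89 at least 2.59-fold and Bhlha15 at least 2.47-fold. Pcdha9 differed by only -0.74 on the B slide and did not pass without null-partner tumor cells A (adjusted p = 0.116) or B (adjusted p = 0.0851) or without tumor cells alone A (-0.97, adjusted p = 0.0712).

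All 28 interferon-stimulated genes rose in tumor cells with null MEFs (28 over the list alone), with a median of 5.48, and camera gave adjusted p = 3.55e-57, or adjusted p = 0.0432 with an estimated correlation. Oas1a rose by 7.15 ± 0.11 and Ifit1 by 7.23 ± 0.14. At the group mean Irf7 reached 14.37 in these tumor cells, above 12.48 in null MEFs sorted from co-culture, and Zbp1 reached 14.2 against 10.39. Those profiled MEFs had no mitomycin, whereas the MEFs grown with these tumor cells did, per the labels. Less the level in tumor cells alone, the median gene lay at 146.9% (A) and 167.8% (B) of the null MEF level, and MEF-typical genes lay at 10.11% and 25.14%.

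**Figure D3:**
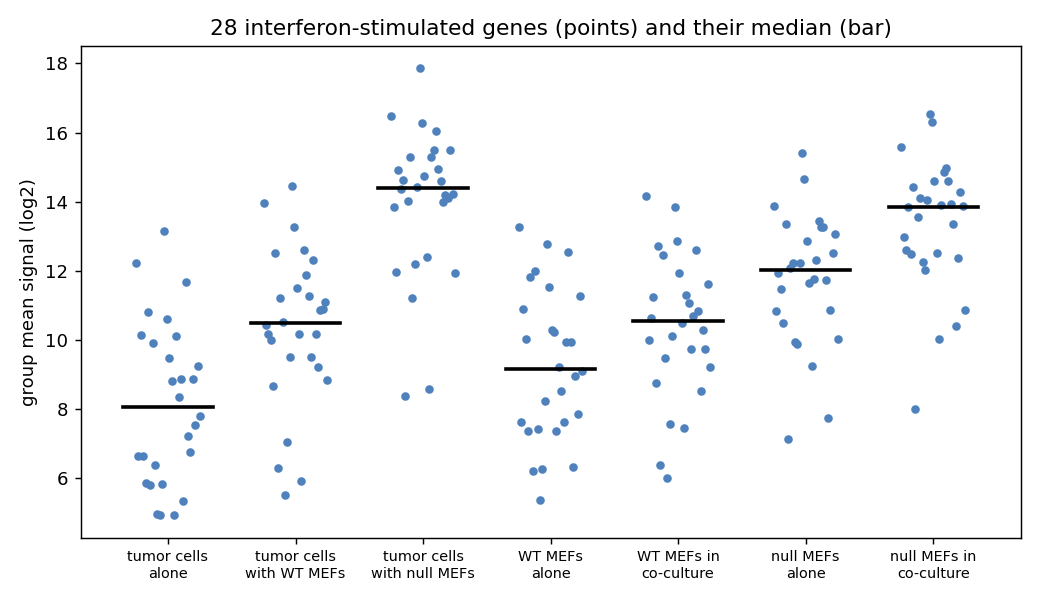
Group mean log2 signal of 28 interferon-stimulated genes (points) and their median (bar) in the 7 groups. In tumor cells with null MEFs all 28 lie above their level in tumor cells alone, as Irf7 does at 14.37 against 5.85.

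Inflammatory genes had 11 of 19 higher and 0 lower with null MEFs (11 and 2 over the list alone), with Saa3 at 4.51 ± 0.22 and Il6 at 4.52 ± 0.89. The list median was 0.85 (adjusted p = 3.5e-09, 0.153 with an estimated correlation). Cholesterol synthesis genes had 13 of 21 lower and 0 higher (18 and 0), with a median of -0.65 and adjusted p = 5.49e-07, or adjusted p = 0.153 with an estimated correlation. Insig1 fell by 0.90 ± 0.17 and Lss by 0.78 ± 0.16. DNA replication genes had 6 of 24 lower (9 over the list alone), such as Cdc6 (-0.69 ± 0.17), with a median of -0.32 and adjusted p = 0.00112, or adjusted p = 0.137 with an estimated correlation. Among mitosis genes 5 of 24 were lower (6), such as Foxm1 (-0.69 ± 0.17), with a median of -0.19 and adjusted p = 0.0258, or adjusted p = 0.42 with an estimated correlation. The p53 targets had 6 of 19 higher and 2 lower (6 and 2), with Pmaip1 at 2.77 ± 0.23 and Gdf15 at 1.35 ± 0.15. Its median was 0.33 (adjusted p = 0.00408, 0.313 with an estimated correlation).

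Collagen and matrix genes had 13 of 23 higher and 0 lower with null MEFs (13 and 0 over the list alone), Col1a1 at 6.52 ± 0.35 among them. The list median was 0.97 (adjusted p = 1.53e-10, 0.153 with an estimated correlation). Fibroblast markers had 7 of 19 higher and 0 lower (7 and 0), such as Dcn (3.26 ± 0.32). Its median was 0.33 (adjusted p = 4.66e-06, 0.176 with an estimated correlation). Proteases had 10 of 18 higher and 1 lower (11 and 3), such as Adamts5 (1.84 ± 0.24). The list median was 0.59 (adjusted p = 0.000132, 0.137 with an estimated correlation). TGF-beta response genes had 8 of 16 higher and 2 lower (8 and 2), such as Tgfbi (3.44 ± 0.31). Its median was 0.70 (adjusted p = 0.000267, 0.222 with an estimated correlation). EMT regulators had 5 of 13 higher and 0 lower (5 and 1), with Twist2 at 4.77 ± 0.35. The list median was 0.10 (adjusted p = 0.048, 0.222 with an estimated correlation). The 18 collagen genes at least 2-fold higher in null MEFs lay at 10.33% and 45.02% of their null MEF level in the 2 arrays. Krt19, a keratin gene that was higher in null than in WT MEFs, rose by 6.39 ± 0.27. Cytosolic heat shock genes did not pass as a list (1 of 21 higher and 5 lower, adjusted p = 0.224).

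With null MEFs 5097 of 25827 genes passed, 2611 higher (51.2%) and 2486 lower, of which 1358 and 199 changed at least 2-fold. The slide block gave 6558, the 12 sound scanner arrays 1353 (94.2% higher, median shift -0.211) and all 14 scanner files 114. With each cell type fitted alone 2245 passed (68.7% higher), and Hsf1, Tgfb3, Pcdha9, Vmn2r11, Bhlha15 and the list of EMT regulators did not. Without the genes at least 2-fold higher in MEFs 2783 passed, 29.2% of them higher. With the MEF share subtracted 3269 passed, 20 of 24 named genes kept their call, Hsf1, Tgfb3, Pcdha9 and Col3a1 (2.33, adjusted p = 0.384) did not, and the lists of mitosis genes (adjusted p = 0.624) and EMT regulators (adjusted p = 0.095) did not pass. Those 2 lists also failed without null-partner tumor cells B (adjusted p = 0.151 and 0.0643) and without tumor cells alone B (0.0688 and 0.077), the EMT regulators failed with the slide block (0.0644), and the proteases failed on the 12 scanner arrays (0.144).

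The 2 responses of the tumor cells overlapped: 1162 genes rose and 701 fell with both kinds of MEFs, against 184 and 118.5 expected for independent lists, and 20 moved in opposite directions. Both share the tumor cells grown alone, which can add to this overlap. With carry-over subtracted the overlap of calls, tumor cells, was 666 in place of 1863, and with each cell type fitted alone 710. The correlation of the 2 responses across genes was 0.697, and 0.498 in simulated unchanged data with the same shared arrays; genes are not independent replicates. Macc1 and Edn1 fell with either partner, and Ccl7 rose with either.

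Tumor cells with WT MEFs were then compared directly with tumor cells with null MEFs. Oas2 (-6.41 ± 0.16, adjusted p = 1.61e-08), Irf7 (-5.72 ± 0.29), Ifi44 (-5.43 ± 0.20), Oas3 (-5.17 ± 0.16), Mx1 (-5.14 ± 0.24), Zbp1 (-4.995 ± 0.17), Ifit3 (-4.94 ± 0.22) and Mx2 (-4.92 ± 0.23) were the lowest. Rsad2 was at least 51.9-fold lower, Ripk4 at least 38.5-fold and Ubd at least 28.4-fold. Penk, which encodes proenkephalin, was higher by 7.79 ± 1.21 (adjusted p = 0.00261), Sfrp2 by 5.57 ± 1.34, Igfbp2 by 4.28 ± 0.71, Rftn1 by 3.85 ± 0.61, Grem1 by 3.81 ± 0.61, Dlk1 by 2.95 ± 0.44, Gas6 by 2.94 ± 0.51 and Omd by 2.90 ± 0.24. Thy1 was at least 55.8-fold higher, Cxcl15 at least 15.1-fold and Fbxl7 at least 5.86-fold. Sfrp2 did not pass without any 1 of its 4 arrays (adjusted p from 0.0528 to 0.122, at 4.80 to 6.35), and Cxcl15 did not without tumor cells with WT MEFs A (3.95, adjusted p = 0.0517) or B (3.88, adjusted p = 0.0587). Of the 2456 genes that passed, 1832 differed in the same direction between co-cultured WT and null MEFs.

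All 28 interferon-stimulated genes were lower with WT than with null MEFs (28 over the list alone), with a median of -3.34 and adjusted p = 4.35e-63, or adjusted p = 0.0327 with an estimated correlation. Inflammatory genes had 8 of 19 lower and 0 higher (9 and 0), with Ccl7 at -4.03 ± 0.42, Saa3 at -2.89 ± 0.22 and Ptgs2 at -2.33 ± 0.24. Its median was -0.50 (adjusted p = 3.24e-08, 0.258 with an estimated correlation). Hypoxia and glycolysis genes had 8 of 25 lower and 1 higher (12 and 1), with Ndrg1 at -1.28 ± 0.12, Bnip3 at -1.04 ± 0.10 and Car9 at 1.47 ± 0.16. The list median was -0.41 (adjusted p = 1.22e-06, 0.0461 with an estimated correlation). Cholesterol synthesis genes had 8 of 21 higher and 0 lower (13 and 0), with Cyp51 at 0.88 ± 0.18 and Hmgcs1 at 0.78 ± 0.15. Its median was 0.48 (adjusted p = 1.39e-07, 0.167 with an estimated correlation). The p53 targets had 5 of 19 lower and 1 higher (5 and 1), with Gdf15 at -1.65 ± 0.15, a median of -0.21 and adjusted p = 0.0395, or adjusted p = 0.57 with an estimated correlation. Fibroblast markers had 5 of 19 higher and 1 lower (9 and 2), with Pdgfrb at 2.01 ± 0.16 and Twist2 at -1.84 ± 0.35, a median of 0.29 and adjusted p = 0.0395, or adjusted p = 0.57 with an estimated correlation. Outside these lists that passed, Cryab was lower by -1.43 ± 0.13 and Atf3 by -2.13 ± 0.35.

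In this direct comparison 2456 genes passed, 1063 higher (43.3%) with WT MEFs and 1393 lower, of which 196 and 764 differed at least 2-fold. With the slide as a block 3311 passed, with the 12 sound scanner arrays 730 (9.9% higher, median shift 0.285) and with all 14 scanner files 1. With each cell type fitted alone 919 passed (31.9% higher), and Tgfb2, Sfrp2 and the list of p53 targets did not. With the MEF shares subtracted 2435 passed, but the split became 53.1% higher, and Sfrp2, Igfbp2, Gas6, Cxcl15, Cxcl12, Tgfb2 and Fbxl7 lost their calls, as did the p53 targets (adjusted p = 0.185) and fibroblast markers (adjusted p = 0.289). The fibroblast markers also failed with the slide block (0.0646), on the 12 scanner arrays (0.926) and without tumor cells with WT MEFs A (0.0621) or null-partner tumor cells A (0.837), the p53 targets without tumor cells with WT MEFs B (0.124) or null-partner tumor cells B (0.426), and the hypoxia genes on the 12 scanner arrays (0.129).

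**Figure D4:**
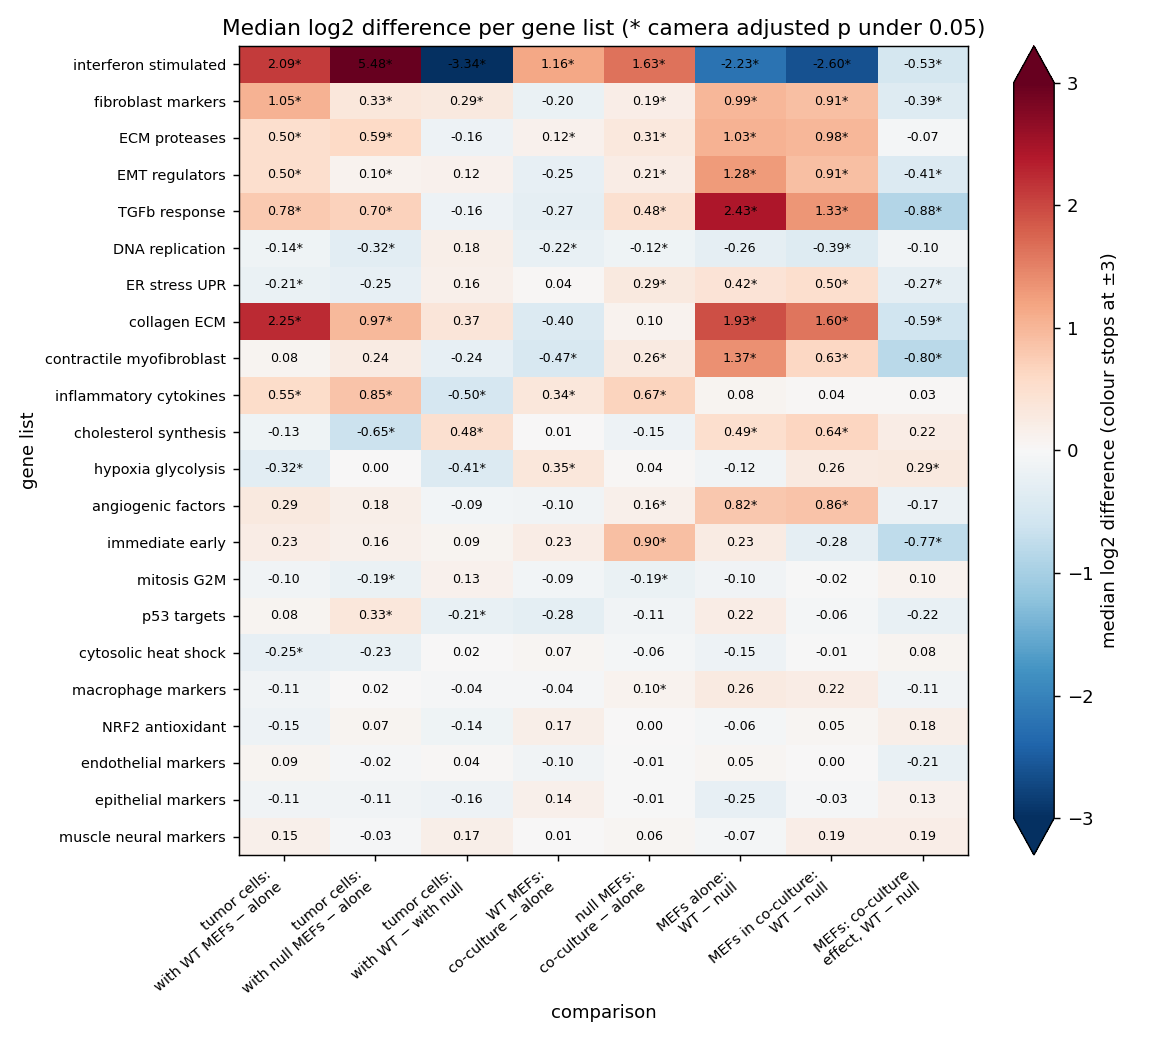
Median log2 difference of each of the 22 gene lists in the 8 comparisons, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Interferon-stimulated genes range from -3.34 to 5.48.

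Genes of secreted signals chosen beforehand were followed in all groups. Cxcl12, a chemokine of fibroblasts, was higher in WT than in null MEFs by 3.14 ± 0.17 alone (8.84-fold, adjusted p = 2.62e-07) and by 3.22 ± 0.17 in co-culture (9.28-fold, adjusted p = 6.21e-07). In tumor cells Cxcl12 rose by 0.89 ± 0.17 with WT MEFs (adjusted p = 0.00651) and did not change with null MEFs (-0.25 ± 0.17, adjusted p = 0.322), a difference of 1.14 ± 0.17 (adjusted p = 0.00185). With the MEF share subtracted the rise of Cxcl12 was -1.56 (adjusted p = 0.00742) and the difference no longer passed (-0.79, adjusted p = 0.0913), and without tumor cells alone A the rise was 0.79 (adjusted p = 0.0519). Tgfb1 was higher in WT than in null MEFs by 1.76 ± 0.18 alone (3.39-fold, adjusted p = 2.05e-05) and by 1.61 ± 0.18 in co-culture. Tgfb1 rose in co-culture by 0.75 ± 0.18 in WT MEFs (adjusted p = 0.0214), by 0.90 ± 0.18 in null MEFs (adjusted p = 0.0171) and by 0.67 ± 0.18 in tumor cells with WT MEFs (adjusted p = 0.0336). None of these 3 increases passed after subtraction (adjusted p = 0.189, 0.305 and 0.0874). The rise of Tgfb1 failed in WT MEFs without their co-culture B (0.57, adjusted p = 0.188) or their culture alone A (adjusted p = 0.156), and in null MEFs without their co-culture B (0.73, adjusted p = 0.127) or their culture alone A (adjusted p = 0.165). In tumor cells Tgfb1 failed without any 1 of its 4 arrays (adjusted p from 0.0567 to 0.185).

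Tgfb3 was higher in WT than in null MEFs by 1.78 ± 0.21 alone (adjusted p = 6.15e-05) and by 1.12 ± 0.21 in co-culture (adjusted p = 0.0019). It rose in tumor cells by 1.46 ± 0.21 with WT MEFs (adjusted p = 0.0012) and by 0.87 ± 0.21 with null MEFs (adjusted p = 0.0142). The latter change of Tgfb3 was -0.09 after subtraction and did not pass without null-partner tumor cells B (0.52, adjusted p = 0.0912) or tumor cells alone A (0.78, adjusted p = 0.0755). Tgfb2 fell in tumor cells with WT MEFs by 0.96 ± 0.26 (adjusted p = 0.0389) and was lower there than with null MEFs (-0.94 ± 0.26, adjusted p = 0.0484). The fall of Tgfb2 did not pass without tumor cells with WT MEFs A (adjusted p = 0.159) or B (adjusted p = 0.101) or tumor cells alone A (adjusted p = 0.117) or B (adjusted p = 0.128), and was -2.98 after subtraction. The difference of Tgfb2 between partners did not pass after subtraction (adjusted p = 0.871), without tumor cells with WT MEFs A (adjusted p = 0.183) or B (adjusted p = 0.125), or without null-partner tumor cells B (-0.49, adjusted p = 0.244). Cxcr4, the receptor of Cxcl12, was well above background in null MEFs only, at least 2.53-fold above WT MEFs alone (adjusted p = 0.000408) and at least 2.15-fold in co-culture (adjusted p = 0.00192).

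The MEF side of the co-culture was tested next, first in WT MEFs. Wfdc2 rose by 8.27 ± 0.16 (309-fold, adjusted p = 3.49e-10), the keratin gene Krt18 by 8.25 ± 0.22, Mgst2 by 7.30 ± 0.13, Tnnt2 by 7.11 ± 0.17, Tas2r113 by 6.95 ± 0.41, Cyb561 by 6.77 ± 0.19, Hamp2 by 6.63 ± 0.18 and Aspa by 6.38 ± 0.10. Mmp10 rose at least 77.5-fold, Cadm1 at least 41.8-fold and Prss46 at least 37.6-fold. Zcchc5 (-2.18 ± 0.30), the Wnt inhibitor gene Wif1 (-2.12 ± 0.20), Emid2 (-2.03 ± 0.18), Cabp5 (-2.03 ± 0.18), Clec3b (-1.82 ± 0.22), Skor1 (-1.75 ± 0.27) and the glucose transporter gene Slc2a4 (-1.70 ± 0.19) fell. Klra1 fell at least 2.82-fold, Olfr1233 at least 2.71-fold and Hey2 at least 2.07-fold. In WT MEFs from co-culture the 45 genes at least 32-fold higher in tumor cells lay at a median of 33.3% (A) and 30.6% (B) of their tumor-cell level.

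Of 28 interferon-stimulated genes 19 rose in WT MEFs and 0 fell (20 and 0 over the list alone), with Ifit1 at 2.35 ± 0.14 and Oas1a at 2.11 ± 0.11, a median of 1.16 and adjusted p = 3.44e-19, or adjusted p = 0.206 with an estimated correlation. Proteases had 5 of 18 higher and 1 lower (8 and 3), with Mmp3 at 4.03 ± 0.11 (adjusted p = 3.66e-09), Mmp13 at 3.23 ± 0.20 and Adamts1 at -0.89 ± 0.19, a median of 0.12 and adjusted p = 0.00866, or adjusted p = 0.29 with an estimated correlation. Hypoxia and glycolysis genes had 8 of 25 higher and 2 lower (11 and 3), with Bnip3 at 1.27 ± 0.10 and Car9 at -1.07 ± 0.16, a median of 0.35 and adjusted p = 0.00419, or adjusted p = 0.206 with an estimated correlation. Inflammatory genes had 5 of 19 higher and 0 lower (5 and 1), with Lcn2 at 3.44 ± 0.24 and Il11 at 1.28 ± 0.14, a median of 0.34 and adjusted p = 0.000186, or adjusted p = 0.391 with an estimated correlation. DNA replication genes had 3 of 24 lower (6 over the list alone), such as Prim1 (-0.51 ± 0.11), a median of -0.22 and adjusted p = 0.00506, or adjusted p = 0.206 with an estimated correlation. Contractile genes had 1 of 12 lower (3), Actg2 (-0.99 ± 0.27), a median of -0.47 and adjusted p = 0.0229, or adjusted p = 0.402 with an estimated correlation. Muscle and neural markers did not pass as a list (2 of 8 higher, 2 lower, adjusted p = 0.706), although Sox2 rose by 4.52 ± 0.22, and endothelial markers did not (0 of 7 higher, 1 lower, adjusted p = 0.159). Epithelial markers had 4 of 18 higher and 2 lower, a median of 0.14 and adjusted p = 0.0916 (0.391 with an estimated correlation), and did not pass as a list. Heat shock genes had Hspa4l higher (2.82-fold, adjusted p = 2.85e-05) and Cryab lower (-0.77 ± 0.13) among 21, and did not pass as a list (adjusted p = 0.286).

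In WT MEFs 2720 genes passed, 1634 higher (60.1%) and 1086 lower, of which 804 and 188 changed at least 2-fold. The slide block gave 3618, the 12 sound scanner arrays 815 (88.3% higher, median shift -0.149) and all 14 scanner files 182. After subtraction of the tumor-cell share 1905 passed, 34.3% higher, 19 of 23 named genes kept their call, Tas2r113, set to the floor, passed as lower (-2.10), Tgfb1, Cadm1 (-0.65) and Prss46 no longer passed, and the contractile list did not pass (adjusted p = 0.657). Subtraction moved the median of the hypoxia list to -0.07, with 4 of 25 higher and 1 lower. It left 11 of 24 DNA replication genes lower (median -0.60) and 18 of 24 mitosis genes lower (median -0.79, adjusted p = 9.37e-16), against 1 lower and a median of -0.09 for mitosis without it. The contractile list also failed without WT MEFs alone B (0.0765), and on the 12 scanner arrays it (0.0883), DNA replication (0.0816) and hypoxia (0.635) failed.

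Null MEFs changed fewer genes in co-culture, and nearly all of these rose. Spp1, the gene of osteopontin, rose by 6.42 ± 0.26 (85.7-fold, adjusted p = 1.15e-07), Aldh3a1 by 6.33 ± 0.21, Wfdc2 by 5.82 ± 0.16, Mgst2 by 5.37 ± 0.13, Col4a5 by 5.25 ± 0.15, Cyp1b1 by 5.07 ± 0.20, Aqp5 by 4.91 ± 0.15 and Aspa by 4.88 ± 0.10. Pitx1 rose at least 17.6-fold, Pkd1l2 at least 15.7-fold and Stab1 at least 14.9-fold. Hist2h2aa1 (-1.55 ± 0.30), Dapl1 (-1.24 ± 0.12), Klk8 (-1.22 ± 0.17), Cabp5 (-1.20 ± 0.18), Hist1h1a (-1.16 ± 0.15), Meox1 (-1.14 ± 0.17), Dcaf12l2 (-1.14 ± 0.22) and Igfbp5 (-1.13 ± 0.18) fell, and Odf1 fell at least 2.95-fold. Tumor-typical genes lay at 6.07% and 6.64% of their tumor-cell level in these arrays. Hist2h2aa1 did not pass without null MEFs with tumor cells A (-1.03, adjusted p = 0.0755) or null MEFs alone A (adjusted p = 0.144) or B (adjusted p = 0.079), nor Dcaf12l2 without null MEFs alone A (adjusted p = 0.0898) or B (adjusted p = 0.114). Igfbp5 did not pass without null MEFs alone A (-1.03, adjusted p = 0.0508), nor Odf1 without null MEFs with tumor cells B (-1.44, adjusted p = 0.103).

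Of 28 interferon-stimulated genes 24 rose in null MEFs and 0 fell (28 and 0 over the list alone), with Zbp1 at 2.65 ± 0.17 and Oasl1 at 2.15 ± 0.13, a median of 1.63 and adjusted p = 5.88e-57, or adjusted p = 0.0218 with an estimated correlation. Immediate early genes had 4 of 20 higher (12 over the list alone), Fosl1 at 1.95 ± 0.14, Klf4 at 1.65 ± 0.22, Dusp1 at 1.52 ± 0.29 and Jun at 1.36 ± 0.30, a median of 0.90 and adjusted p = 1.21e-13, or adjusted p = 0.0926 with an estimated correlation. Inflammatory genes had 8 of 19 higher (8), with Cxcl5 at 2.60 ± 0.34 and Vcam1 at 1.31 ± 0.12, a median of 0.67 and adjusted p = 8.51e-12, or adjusted p = 0.0826 with an estimated correlation. TGF-beta response genes had 4 of 16 higher (8), with Ltbp2 at 3.68 ± 0.20, a median of 0.48 and adjusted p = 2.05e-10, or adjusted p = 0.0581 with an estimated correlation. ER stress genes had 2 of 16 higher (3), Trib3 at 1.62 ± 0.19 and Chac1 at 0.90 ± 0.15. Its median was 0.30 (adjusted p = 2.72e-07, 0.0218 with an estimated correlation). Proteases had 4 of 18 higher (7), with Mmp10 at 2.75 ± 0.22. Its median was 0.31 (adjusted p = 2.72e-07, 0.0313 with an estimated correlation). EMT regulators had 4 of 13 higher (4), with Snai1 at 1.23 ± 0.15. Its median was 0.21 (adjusted p = 8.58e-06, 0.0313 with an estimated correlation).

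Angiogenic factors had 3 of 16 higher in null MEFs (5 over the list alone), with Pgf at 1.82 ± 0.22. Its median was 0.16 (adjusted p = 7.21e-05, 0.0826 with an estimated correlation). Mitosis genes had 0 of 24 past the gene test, a median of -0.19 and adjusted p = 0.00024, or adjusted p = 0.23 with an estimated correlation. Contractile genes had 0 of 12 past it (1 higher over the list alone), a median of 0.26 and adjusted p = 0.00847, or adjusted p = 0.231 with an estimated correlation. Fibroblast markers had 5 of 19 higher and 1 lower (5 and 1), with Pdgfrb at 1.26 ± 0.16, a median of 0.19 and adjusted p = 0.0116, or adjusted p = 0.354 with an estimated correlation. DNA replication genes had 1 of 24 lower (1), Ccne1 (-0.41 ± 0.09), a median of -0.12 and adjusted p = 0.0116, or adjusted p = 0.119 with an estimated correlation. Macrophage markers had 1 of 9 higher (2), Cd14 at 4.63 ± 0.14, a median of 0.10 and adjusted p = 0.044, or adjusted p = 0.119 with an estimated correlation. The contractile, DNA replication, fibroblast and macrophage lists did not pass without null MEFs with tumor cells A (adjusted p = 0.0682, 0.237, 0.306 and 0.0885), the array that also held mRNA typical of WT MEFs. Without null MEFs alone A the contractile and DNA replication lists (each 0.0515) and the macrophage markers (0.0597) did not pass, nor did the latter without null MEFs with tumor cells B (0.0932). Cytosolic heat shock genes did not change as a list (1 of 21 higher, median -0.06, adjusted p = 0.987).

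In null MEFs 815 genes passed, 729 higher (89.4%) and 86 lower, of which 475 and 14 changed at least 2-fold. With the slide block 1004 passed, with the 12 sound scanner arrays 337 (99.4% higher, median shift -0.143) and with all 14 scanner files 71. With each cell type fitted alone 895 passed, and Hsf1, Tgfb1, Dcaf12l2, Odf1 and the list of macrophage markers did not. After subtraction 364 passed, 16 of 22 named genes kept their call, Wfdc2, set to the floor, passed as lower (-1.44), Hsf1, Tgfb1, Hist2h2aa1, Dcaf12l2 and Pitx1 no longer passed, and the macrophage list did not pass (adjusted p = 0.109), nor did it with the slide block (0.0577). On the 12 scanner arrays the contractile (0.524), EMT (0.0913), fibroblast (0.301) and macrophage (0.0889) lists failed.

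WT and null MEFs grown alone were compared next, with the most genes passing (8741). Subtraction changed co-culture arrays only, yet left 7262 here and 8144 in co-culture. Higher in WT MEFs were Nts (8.95 ± 1.06, adjusted p = 7.11e-05), the Wnt antagonist gene Dkk3 (8.88 ± 1.18), Thy1 (433-fold, adjusted p = 0.000111), Msmp (7.95 ± 0.84), Penk (7.78 ± 1.21), Cxcl15 (7.63 ± 0.78), Col4a5 (7.55 ± 0.15) and Rftn1 (128-fold, adjusted p = 7.45e-06). Vat1l was at least 380-fold higher, Pitx1 at least 237-fold and Alx1 at least 156-fold. Lower in WT MEFs were Susd4 (-6.94 ± 0.36), Pgam2 (-6.67 ± 0.30), the junction genes F11r (-6.64 ± 0.23), Cgn (-6.22 ± 0.21) and Lsr (-5.95 ± 0.38), Fam174b (-5.92 ± 0.22), Oas1a (-5.81 ± 0.11) and Selenbp1 (-5.63 ± 0.29). Il28ra was at least 85.6-fold lower and Grhl3, an epithelial transcription factor gene, at least 78.4-fold.

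Interferon-stimulated genes had 27 of 28 lower in WT MEFs alone (27 over the list alone), with Usp18 at -4.83 ± 0.21, a median of -2.23 and adjusted p = 6.36e-19, or adjusted p = 0.127 with an estimated correlation. Collagen and matrix genes had 17 of 23 higher and 2 lower (17 and 2), with Eln at 6.81 ± 0.68 and Bgn at 5.53 ± 0.43, a median of 1.93 and adjusted p = 7.42e-08, or adjusted p = 0.234 with an estimated correlation. TGF-beta response genes had 14 of 16 higher and 1 lower (14 and 1), with Ltbp2 at 5.62 ± 0.20 and Tgfbi at -5.01 ± 0.31, a median of 2.43 and adjusted p = 1.6e-07, or adjusted p = 0.127 with an estimated correlation. EMT regulators had 11 of 13 higher and 1 lower (12 and 1), with Snai1 at 2.15 ± 0.15, a median of 1.28 and adjusted p = 7.33e-07, or adjusted p = 0.0528 with an estimated correlation. Contractile genes had 10 of 12 higher and 1 lower (10 and 1), with Actg2 at 5.46 ± 0.27, a median of 1.37 and adjusted p = 1.28e-05, or adjusted p = 0.127 with an estimated correlation. Fibroblast markers had 11 of 19 higher and 3 lower (12 and 3), with Fbln2 at 4.42 ± 0.14, a median of 0.99 and adjusted p = 8.92e-05, or adjusted p = 0.234 with an estimated correlation.

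ER stress genes had 7 of 16 higher and 1 lower in WT MEFs alone (9 and 1 over the list alone), with Trib3 at 4.25 ± 0.19, a median of 0.42 and adjusted p = 9.6e-05, or adjusted p = 0.0528 with an estimated correlation. Cholesterol synthesis genes had 10 of 21 higher and 1 lower (11 and 1), with Mvk at 1.22 ± 0.12, a median of 0.49 and adjusted p = 0.00155, or adjusted p = 0.236 with an estimated correlation. Angiogenic factors had 10 of 16 higher and 4 lower (10 and 4), with Edn1 at 3.36 ± 0.25, a median of 0.82 and adjusted p = 0.0135, or adjusted p = 0.234 with an estimated correlation. Proteases had 9 of 18 higher and 5 lower (11 and 5), with Mmp2 at 5.37 ± 0.33 and Mmp13 at -3.72 ± 0.20, a median of 1.03 and adjusted p = 0.0193, or adjusted p = 0.234 with an estimated correlation. Cytosolic heat shock genes did not pass (median -0.15, adjusted p = 0.632): 4 of 21 were higher, such as Hsph1 (1.60 ± 0.17), and 4 lower, such as Hspb8 (-1.18 ± 0.11). Epithelial markers had 2 of 18 higher and 5 lower, with Krt19 at -3.13 ± 0.27, and did not pass as a list (adjusted p = 0.308).

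Between MEFs grown alone 8741 genes passed, 4108 higher (47%) in WT MEFs and 4633 lower, of which 1820 and 1589 differed at least 2-fold. The slide block gave 9932, the 12 sound scanner arrays 3565 and all 14 scanner files 495. All 27 named genes that passed also passed on the 12 scanner arrays, and the protease list did not (adjusted p = 0.589). Each genotype was 1 MEF stock as far as the labels state, so differences between stocks other than Hsf1 were not separated.

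The 2 kinds of MEFs were also compared in co-culture. Higher in WT MEFs were Cxcl15 (6.18 ± 0.78), Penk (5.61 ± 1.21), Msmp (5.33 ± 0.84), the fibrillin gene Fbn2 (32-fold, adjusted p = 0.000608), Rftn1 (4.90 ± 0.61), Slc22a17 (4.76 ± 0.46), Cxcl5 (4.72 ± 0.34) and Cav3 (4.55 ± 0.38). The A array of null MEFs with tumor cells held mRNA typical of WT MEFs, and all 8 of these genes differed less on the A than on the B slide. The largest gaps were 2.96 and 8.25 for Penk, 4.45 and 7.90 for Cxcl15, 3.34 and 7.32 for Msmp, 3.46 and 6.54 for Fbn2, and 3.58 and 6.22 for Rftn1. Il20ra was at least 11.4-fold higher, Cacna2d3 at least 7.47-fold and Lgr5 at least 6.79-fold. Lower were Susd4 (-6.99 ± 0.36), Lsr (-6.26 ± 0.38), Rsad2 (-6.26 ± 0.31), Cited1 (-6.21 ± 0.35), Pgam2 (-6.15 ± 0.30), Oas2 (-6.12 ± 0.16), Fam174b (64.1-fold lower) and Cgn (-5.79 ± 0.21), with adjusted p from 2.58e-08 for Oas2 to 1.38e-06 for Lsr. Il28ra was at least 83.4-fold lower, Bex1 at least 54.3-fold and Grhl3 at least 49.4-fold.

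All 28 interferon-stimulated genes were lower in co-cultured WT than null MEFs (28 over the list alone), with a median of -2.60 and adjusted p = 2.24e-28, or adjusted p = 0.0659 with an estimated correlation. Collagen and matrix genes had 16 of 23 higher and 1 lower (17 and 1), with Thbs2 at 3.83 ± 0.18, a median of 1.60 and adjusted p = 2.64e-07, or adjusted p = 0.16 with an estimated correlation. Cholesterol synthesis genes had 13 of 21 higher and 0 lower (14 and 0), with Mvd at 1.12 ± 0.16, a median of 0.64 and adjusted p = 3.97e-06, or adjusted p = 0.122 with an estimated correlation. Proteases had 12 of 18 higher and 1 lower (12 and 2), with Mmp10 at 2.43 ± 0.22, a median of 0.99 and adjusted p = 7.45e-06, or adjusted p = 0.0613 with an estimated correlation. EMT regulators had 10 of 13 higher and 0 lower (10 and 0), with Snai1 at 1.74 ± 0.15, a median of 0.91 and adjusted p = 1.76e-05, or adjusted p = 0.0613 with an estimated correlation. Fibroblast markers had 11 of 19 higher and 3 lower (12 and 3), with Mfap5 at 2.70 ± 0.17, a median of 0.91 and adjusted p = 4.68e-05, or adjusted p = 0.16 with an estimated correlation.

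TGF-beta response genes had 11 of 16 higher and 1 lower in co-cultured WT MEFs (12 and 1 over the list alone), with Pmepa1 at 2.42 ± 0.16, a median of 1.34 and adjusted p = 5.32e-05, or adjusted p = 0.16 with an estimated correlation. Angiogenic factors had 10 of 16 higher and 2 lower (10 and 2), with Adm at 3.63 ± 0.39. Its median was 0.86 (adjusted p = 0.00038, 0.122 with an estimated correlation). ER stress genes had 10 of 16 higher and 1 lower (11 and 1), with Trib3 at 2.06 ± 0.19 and Atf3 at -2.77 ± 0.35. Its median was 0.50 (adjusted p = 0.00038, 0.0613 with an estimated correlation). DNA replication genes had 1 of 24 higher and 11 lower (1 and 12), with Mcm3 at -0.99 ± 0.16. Its median was -0.39 (adjusted p = 0.000775, 0.0783 with an estimated correlation). Contractile genes had 7 of 12 higher and 1 lower (8 and 1), with Cnn1 at 1.89 ± 0.32. Its median was 0.63 (adjusted p = 0.00124, 0.16 with an estimated correlation). Between co-cultured MEFs 7637 genes passed, 3816 higher (50%) and 3821 lower, of which 1409 and 1255 differed at least 2-fold. The slide block gave 8900, the 12 scanner arrays 2675, all 14 files 74 and subtraction 8144, with all 27 named genes. Subtraction left 18 of 24 DNA replication and 12 of 24 mitosis genes lower, against 11 and 3.

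The last test asked whether co-culture changed WT and null MEFs differently. Cyb561, Mmp3 and Perp rose more in WT MEFs, and Col4a5 and Cyp1b1 rose more in null MEFs. The difference was 6.02 ± 0.27 for Cyb561 (adjusted p = 1.67e-06), 4.63 ± 0.59 for Tas2r113, 4.12 ± 0.19 for the cyclooxygenase gene Ptgs1, 3.85 ± 0.25 for Perp, 3.71 ± 0.25 for Tnnt2, 3.70 ± 0.21 for Gng2, 3.64 ± 0.16 for Ica1 and 3.32 ± 0.16 for Mmp3. It was -5.57 ± 0.21 for Col4a5, -5.10 ± 0.29 for Cyp1b1, -3.26 ± 0.34 for Cyp26b1, -3.02 ± 0.27 for Id4, -2.99 ± 0.53 for the Notch target gene Hes1, -2.87 ± 0.18 for Nr2f1, -2.58 ± 0.46 for Wscd2 and -2.40 ± 0.15 for the cyclin D1 gene Ccnd1. Hes1 did not pass without WT MEFs with tumor cells B (adjusted p = 0.0622), WT MEFs alone A (-2.61, adjusted p = 0.053) or null MEFs alone B (adjusted p = 0.0581). Wscd2 did not without WT MEFs with tumor cells A (-2.48, adjusted p = 0.0553), WT MEFs alone B (adjusted p = 0.0541) or null MEFs alone A (adjusted p = 0.0535).

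TGF-beta response genes had 1 of 16 with a larger and 4 with a smaller change in WT MEFs (1 and 8 over the list alone), with Ltbp2 at -3.30 ± 0.29 and Ctgf at -2.13 ± 0.36, a median of -0.88 and adjusted p = 1.3e-05, or adjusted p = 0.184 with an estimated correlation. Interferon-stimulated genes had 0 of 28 larger and 1 smaller (1 and 8), Stat2 (-1.01 ± 0.21), a median of -0.53 and adjusted p = 3.32e-05, or adjusted p = 0.461 with an estimated correlation. Contractile genes had 2 of 12 smaller (1 larger and 4 smaller over the list alone), with Tpm1 at -0.58 ± 0.13, a median of -0.80 and adjusted p = 7e-05, or adjusted p = 0.184 with an estimated correlation. Immediate early genes had 0 of 20 past the gene test (0 and 7), a median of -0.77 and adjusted p = 7e-05, or adjusted p = 0.461 with an estimated correlation. Hypoxia and glycolysis genes had 3 of 25 larger and 1 smaller (5 and 1), with Bnip3 at 1.34 ± 0.14, a median of 0.29 and adjusted p = 0.0048, or adjusted p = 0.184 with an estimated correlation. Collagen genes had 1 of 23 larger, Lum (2.29 ± 0.20), 0 smaller (1 and 0), a median of -0.59 and adjusted p = 0.00488, or adjusted p = 0.49 with an estimated correlation. ER stress genes had 2 of 16 smaller (4), with Trib3 at -2.19 ± 0.27, a median of -0.27 and adjusted p = 0.00667, or adjusted p = 0.184 with an estimated correlation. EMT regulators had 0 of 13 past the gene test (0), a median of -0.41 and adjusted p = 0.00759, or adjusted p = 0.184 with an estimated correlation. Fibroblast markers had 1 of 19 larger and 3 smaller (1 and 4), with Pdgfrb at -1.39 ± 0.23, a median of -0.39 and adjusted p = 0.0349, or adjusted p = 0.49 with an estimated correlation.

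This difference of responses passed for 784 genes, 508 (64.8%) larger in WT MEFs and 276 smaller, of which 360 and 184 differed at least 2-fold, with 1055 under the slide block and 95 on the 12 sound scanner arrays. After subtraction 213 passed, 91 larger (42.7%) and 122 smaller, and without genes at least 2-fold higher in tumor cells 73 passed, 26 larger (35.6%) and 47 smaller. With subtraction 11 of 16 named genes kept their call, all but Tas2r113, Gng2, Mmp3, Hes1 and Wscd2, and the lists of TGF-beta response (adjusted p = 0.0602), contractile (0.0666), ER stress (0.104), EMT (0.445), collagen (0.583) and fibroblast (0.255) genes did not pass. The collagen and fibroblast lists failed without null MEFs with tumor cells A (0.0635 and 0.198), the fibroblast list also without WT MEFs with tumor cells B (0.0904), WT MEFs alone A (0.0648) or null MEFs alone B (0.0633), and the ER stress list without null MEFs alone A (0.0527). On the 12 scanner arrays the EMT, ER stress and fibroblast (each 0.0906), hypoxia (0.2) and interferon-stimulated (0.379) lists failed. The 2 MEF responses shared 520 genes that rose and 32 that fell, against 46.1 and 3.6 for independent lists, with 10 in opposite directions. With carry-over subtracted the overlap of calls, MEFs, was 230 in place of 552.

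**Figure D5:**
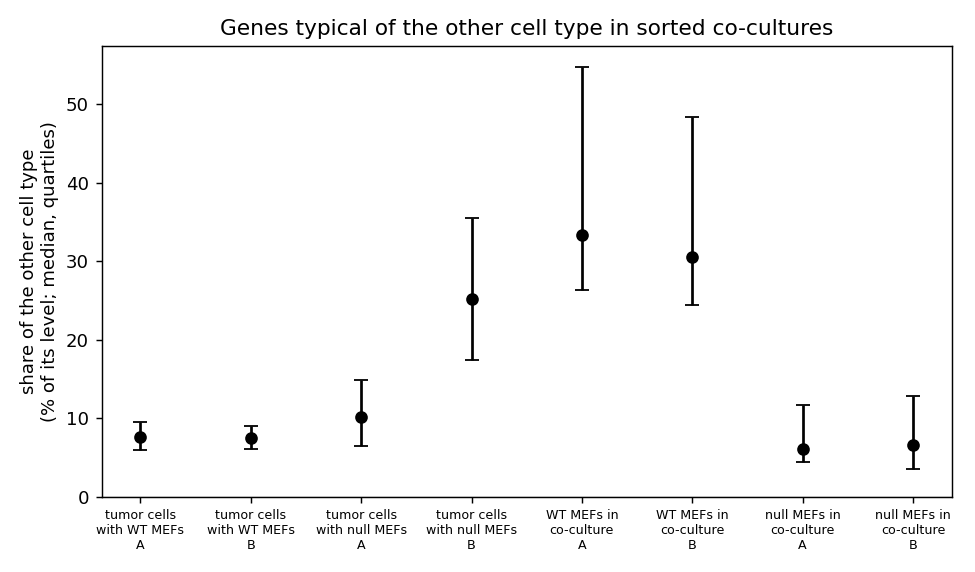
Signal of genes at least 32-fold higher in the other cell type, as a percent of their level there (median and quartiles over 118 MEF-typical or 45 tumor-typical genes), in the 8 sorted co-culture arrays. WT MEFs carried the largest share, 33.3% and 30.6%, and null MEFs 6.07% and 6.64%.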

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

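The tests of interferon-stimulated genes, of mRNA typical of WT MEFs in null MEFs and of carry-over in the difference between partners were chosen in their present form after results were seen, and the other tests of carry-over before.

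Tumor cells with WT MEFs and tumor cells with null MEFs differed in 2456 genes by a test of that difference, and the co-culture responses of WT and null MEFs differed in 784. Among lists, the partners differed for interferon-stimulated (-3.34), inflammatory (-0.50), hypoxia (-0.41), p53 target (-0.21), cholesterol (0.48) and fibroblast (0.29) genes. With an estimated correlation only the interferon-stimulated (adjusted p = 0.0327) and hypoxia (0.0461) lists passed. The MEF responses differed for TGF-beta response (-0.88), contractile (-0.80), immediate early (-0.77), collagen (-0.59), interferon-stimulated (-0.53), EMT (-0.41), fibroblast (-0.39), ER stress (-0.27) and hypoxia (0.29) genes. With an estimated correlation 0 of these 9 passed (adjusted p from 0.184 to 0.49), and 3 passed after carry-over was subtracted.

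Genes that differed between the partners in tumor cells were Penk (7.79), Sfrp2 (5.57), Igfbp2 (4.28), Rftn1 (3.85), Grem1 (3.81), Dlk1 (2.95), Gas6 (2.94), Omd (2.90) and Cxcl12 (1.14), and Thy1, Cxcl15 and Fbxl7 were at least 55.8-fold, at least 15.1-fold and at least 5.86-fold higher with WT MEFs. Lower with WT MEFs were Oas2 (-6.41), Irf7 (-5.72), Ifi44 (-5.43), Oas3 (-5.17), Mx1 (-5.14), Zbp1 (-4.995), Ifit3 (-4.94), Mx2 (-4.92) and Tgfb2 (-0.94), and Rsad2, Ripk4 and Ubd by at least 51.9-fold, at least 38.5-fold and at least 28.4-fold. With carry-over subtracted Sfrp2, Igfbp2, Gas6, Cxcl12, Cxcl15, Fbxl7 and Tgfb2 no longer passed, and Sfrp2, Igfbp2 and Cxcl15 were set to the floor in both groups, so no direction was measured for those 3. Sfrp2 did not pass without any 1 of its 4 arrays, nor Tgfb2 without 3 of its 4. In the MEF responses, Cyb561 (6.02), Tas2r113 (4.63), Ptgs1 (4.12), Perp (3.85), Tnnt2 (3.71), Gng2 (3.70), Ica1 (3.64) and Mmp3 (3.32) rose more in WT MEFs, and Col4a5 (-5.57), Cyp1b1 (-5.10), Cyp26b1 (-3.26), Id4 (-3.02), Hes1 (-2.99), Nr2f1 (-2.87), Wscd2 (-2.58) and Ccnd1 (-2.40) differed the other way. Of these, Tas2r113, Gng2, Mmp3, Hes1 and Wscd2 no longer passed with carry-over subtracted.

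Genes that rose in co-culture may have come from cells of the other type left in the sorted fractions. In tumor cells with WT MEFs, tumor cells with null MEFs and WT MEFs, 94.1%, 76.3% and 77.8% of the genes typical of the other type lay within 2-fold of their median share on the mean of 2 arrays, near what a mixture requires, but on the A array alone 69.5% did in tumor cells with null MEFs and 73.3% in WT MEFs, below the 75% set beforehand. In null MEFs only 57.8% did, so carried-over RNA and induction cannot be told apart for those genes, because their shares spread too widely. RNA with the profile of untreated MEFs or of tumor cells alone was excluded as the whole cause. Of the genes that rose 61.5%, 63.8%, 66.6% and 65.6% lay at least 2-fold higher there (same order). RNA of co-cultured tumor cells was not tested. Of the genes that differed between partners in tumor cells 74.6% had the direction of the MEFs, and 0 others lay within dilution (0.306). The MEF shares differed, so MEF RNA could give either direction and is not excluded here. RNA of mitomycin-treated MEFs, not profiled, and cell responses stay open.

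Interferon-stimulated genes such as Irf7 and Zbp1 rose in tumor cells beyond the share of MEF RNA. Less their level in tumor cells alone, the list's median share was at least 6.68 times the gauge with null MEFs and at least 9.74 times with WT MEFs, which excludes RNA with the profile of the untreated MEFs as the whole source. From array A to B the list rose 1.336-fold with null MEFs, where the gauge genes rose 2.53-fold, and 0.952-fold with WT MEFs, where they changed 0.984-fold. With 1 array at each share, RNA of mitomycin-treated MEFs rich in these mRNAs and a response of the tumor cells cannot be told apart. Genotype and MEF stock are the same split here, so an effect of Hsf1, which may differ from that of the stock, stays untested.

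Genes typical of WT MEFs, Penk and Cxcl15 among them, had signal in null MEFs with tumor cells on the A array only. The 36 genes at least 32-fold higher in WT MEFs alone than in null MEFs and tumor cells alone lay at a median of 9.25% of their WT level there and at -0.18% on the B array. Of 150 further genes 8- to 32-fold higher, 80% lay within 2-fold of their median share on the A array, which is what WT MEF RNA in that sample would give and makes it a candidate source. The share on B was -0.031 times that on A by the choice of pattern, so induction in culture A stays open. No other biological explanation was tested.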

How the results depend on the processing

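The tests with carry-over subtracted, with scanner settings limited to 12 arrays, with the value table under other scaling or on 12 arrays, and without genes higher in the other type were chosen after the data were seen, and the scanner settings themselves before. Counts follow this order: tumor cells with WT MEFs, with null MEFs and between partners; WT and null MEFs with tumor cells; WT against null MEFs alone and in co-culture; and the difference of MEF responses. For the moved counts below the cause was not tested, except where fewer genes or arrays entered.

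With the replicate letter, which is the slide, as a block, the counts were 4163, 6558, 3311, 3618, 1004, 9932, 8900 and 1055, none moved by over 1.5 times, and 73 of 77 list calls were kept. The pairing check gave correlations of replicate deviations from 0.092 to 0.599 over 21 pairs of groups (median 0.299, 20 over 0.1), so A and B share a slide but were not taken as pairs. On the 12 scanner arrays with the replicate block, 1294, 2605, 1520 and 338 genes passed in the first 3 comparisons and the last, with 956 for the overlap of calls, tumor cells.

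The stricter filter (16760 genes) gave 3288, 1366, 1735, 477, 5037 and 505 in comparisons 2 to 5, 7 and 8, because fewer genes were tested. The overlap of calls, tumor cells, was 1229, and the overlap of calls, MEFs, was 314. It ended 12 of 77 list calls: heat shock, DNA replication and ER stress in tumor cells with WT MEFs, EMT with null MEFs, fibroblast markers between partners, contractile, protease and hypoxia genes in WT MEFs, DNA replication in null MEFs, angiogenic genes in MEFs alone, and EMT and hypoxia in the MEF difference. Quantile scaling ended 4, DNA replication and ER stress in tumor cells with WT MEFs, mitosis with null MEFs and macrophage markers in null MEFs. The value table of 12 arrays ended 4, heat shock, DNA replication and ER stress with WT MEFs and fibroblast markers between partners, and the value table minus its 75th percentile ended ER stress with WT MEFs. Each cell type fitted alone gave 1274, 2245 and 919 in tumor cells, with 710 in the tumor-cell overlap. Quantile scaling, an intensity trend, no filter, the value table minus its 75th percentile and the value table of 12 arrays moved no count by over 1.5 times.

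The 12 sound scanner arrays gave 825, 1353, 730, 815, 337, 3565, 2675 and 95, with 604 in the overlap of calls, tumor cells, and 239 in the overlap of calls, MEFs. With quantile scaling they gave 1091, 1699, 1132, 1215, 444, 5649, 4453 and 171 (overlaps 768 and 302). With normexp they gave 393, 831, 489, 610, 251, 3151, 2412 and 75 (282 and 177), and with the mean of probes 700, 1230, 647, 714, 307, 3497, 2618 and 70 (520 and 215). All 14 scanner files, 2 of them faulty, gave 42, 114, 1, 182, 71, 495, 74 and 0 (limma, with 331 at an unadjusted p under 0.05 for the last), overlaps of 37 and 48, and 37 list calls. There Hsf1 in tumor cells with null MEFs was 0.027, which did not pass, and camera's direction was the opposite, without passing, for hypoxia genes in tumor cells with WT MEFs (-0.18), between partners (-0.24), in WT MEFs (-0.45) and in the MEF difference (0.10), and for p53 targets between partners (1.18). For list macrophage_markers in MEF_null_co_minus_alone, null MEFs with tumor cells, the value was -0.291, which did not pass. Fibroblast markers between partners had the opposite direction, without passing, with quantile scaling (median 0.13) and normexp (0.33) of the 12 arrays. Quantile scaling, normexp and probe means were planned for all 14 scanner files and were run on the sound 12, and the planned value table became the setting reported.

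With carry-over subtracted 1310, 3269, 364 and 213 genes passed in comparisons 1, 2, 5 and 8, with 666 in the overlap of calls, tumor cells, and 230 in the overlap of calls, MEFs. By construction this removes the other type's signal and sets what is left below the floor to the floor. Cxcl12 (-1.56) and Rcn3 (-1.33) in tumor cells with WT MEFs, Tas2r113 (-2.10) in WT MEFs and Wfdc2 (-1.44) in null MEFs passed with the opposite sign, the last 3 set to the floor on both co-culture arrays. Fstl1 (-1.27), Wisp2 (-1.52), Bicc1 (-0.28) and Plxdc2 (-0.33) in tumor cells with WT MEFs, Tgfb3 (-0.089) with null MEFs, and Cadm1 (-0.65) in WT MEFs no longer passed. Of these all but Tgfb3 were set to the floor on both co-culture arrays, so the floor set their values. Between partners Cxcl12 (-0.79) and Gas6 (-2.16) no longer passed, nor did Sfrp2, Igfbp2 and Cxcl15 (-0.027 each), set to the floor in both groups so that no direction was measured. The collagen (-0.16) and fibroblast (0.006) lists in the MEF difference had the opposite direction in camera and did not pass. Without genes at least 2-fold higher in the other type, 1472, 2783, 994, 1183, 251 and 73 passed in comparisons 1 to 5 and 8. An estimated correlation left 7 of 77 list calls. A 16-fold gauge gave shares of 8.05% (tumor cells with WT MEFs) and 7.33% (null MEFs). Normexp could use only the B slide and gave 27.74% (WT MEFs) and 27.47% (tumor cells with null MEFs), where the B arrays had 30.58% and 25.14%.

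Leaving out 1 array, with its lone partner assumed to vary like the other groups, gave 1853 to 2393, 2831 to 4547, 1494 to 2445, 1305 to 1590, 537 to 831, 6552 to 6769, 5197 to 6794 and 410 to 1029 genes. The counts moved by over 1.5 times in comparison 1 without tumor cells with WT MEFs A (1869) or B (1853) or tumor cells alone A (1894), where the overlap of calls, tumor cells, was 1159, 1221 and 1211. Over all arrays left out it ranged from 1159 to 2006, and the overlap of calls, MEFs, from 398 to 533. They also moved in comparison 2 without null-partner tumor cells B (2831), in comparison 3 without tumor cells with WT MEFs B (1494), in comparison 4 without any 1 of its 4 arrays, in comparison 5 without null MEFs alone B (537), and in comparison 8 without any WT MEF array or either array of null MEFs alone (410 to 493).

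Of 539 list values under planned settings, all reruns of the value table, 446 kept their side of the threshold and 93 fell below it. Under added settings 550 of 669 kept it, 109 fell below and 10 had the opposite direction. With arrays left out 315 of 344 kept it. Of named genes 1171 of 1192, 1553 of 1944 (16 with the opposite sign) and 903 of 952 kept theirs. Signal over background limits genes near the floor, whose folds are lower bounds.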

Other observations

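These genes were picked after the results were seen (limma, n = 2 and 2). In tumor cells with WT MEFs, Vegfc rose by 4.59 ± 0.36, and with carry-over subtracted its difference was 0.00 (adjusted p = 0.998). Trp53inp1 rose there by 1.99 ± 0.19, and by 1.70 with carry-over subtracted (adjusted p = 5.59e-05). In MEFs with tumor cells Cd14 rose by 3.92 ± 0.14 (WT) and 4.63 ± 0.14 (null), and after subtraction by 2.50 (adjusted p = 0.00167) and 3.27 (adjusted p = 0.000623). Krt8 rose by 2.68 ± 0.13 in WT MEFs and by 2.33 after subtraction (adjusted p = 1.53e-05). Krt18 rose by 7.22 ± 0.22 in null MEFs and by 6.95 after subtraction (adjusted p = 2.7e-07). Angptl4 rose by 2.93 ± 0.28 in WT MEFs, and its subtracted value was -1.49 (adjusted p = 0.323).

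Mean carry-over by group was 7.54% ± 0.15 (SD, n = 2) in tumor cells with WT MEFs, 17.62% ± 10.63 with null MEFs, 31.94% ± 1.93 in WT MEFs and 6.36% ± 0.40 in null MEFs. Replicates of a group correlated across genes with r from 0.993 to 0.997, and the SD of their log2 difference lay between 0.256 and 0.388; genes are not independent replicates. Null-typical genes (16) lay at -0.11% and -0.33% of their null MEF level in WT MEFs with tumor cells. The covariance of the 2 tumor-cell responses was 0.278, against 0.0228 in simulated unchanged data, and that of the 2 MEF responses, which share no arrays, was 0.124.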
